A study of Mus musculus with 2 samples.

How the data were processed

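Polyadenylated RNA of bone marrow derived macrophages from mice of 8 weeks was measured by RNA sequencing in 2 samples of 1 group, numbered biological replicates 1 and 2 per the labels. The labels give an RNA size range above 200 bases and name a spike-in reference. They say nothing of the culture medium, the growth factor or the strand of the library. Both samples carry the same donor record although each is described as from an individual mouse.

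The deposited files are a gene table and a transcript table for each library, made against mm10 with annotation release M4, per the text deposited beside them. The aligner, the quantifier and their versions are not given in the sources used here, and the column names are those that RSEM writes. The expected counts are, per the file headers, estimated read numbers for each gene or transcript that need not be whole, so reads that fit several genes are shared among them. TPM was computed by the authors over all sequences of their tables, including tRNA entries and spike-in sequences, so that it depends on the estimated length of each gene. FPKM was deposited by the authors in the same tables, and served only as an alternative. The deposited percent of each gene's TPM on each transcript was used for isoform shares. Bounds of a credibility interval of posterior mean TPM were deposited too and were treated as a signal whose level of credibility is not given in the sources used here. Posterior means shrink towards a prior that depends on depth, so the bounds of both libraries sit on different scales. In 99.96% of gene rows the length minus the effective length was 29, which implies single reads of 30 bases.

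Totals were 11878065 expected counts in replicate 1 and 7909888 in replicate 2. The tables held 69691 rows: 43346 Ensembl genes, 26248 entries with numeric IDs of a median length of 73 bases, and 97 control sequences. Gene IDs were matched without version to GENCODE M21, which uses the same assembly, and 42462 (98.0%) matched. The 884 unmatched genes held 1.39% and 1.09% of counts, the largest of them with 13477 and 9605 TPM, and were left out. Symbols, gene classes and coordinates are from M21 on mm10, counted from 1. Genes under 200 bases held 7.22% and 8.09% of TPM on 0.271% and 0.305% of counts, since a read on a short entry gives a high TPM. Mitochondrial genes held 5.25% and 5.45% of counts and protein-coding genes 89.4% and 89.3%. An expected count of 0 allows up to 3 counts, or 0.253 and 0.379 counts per 1e6 (CPM), and this floor and the 95% Wilson intervals cover counting error only.

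The sequence that each gene shares with others was measured on the M21 transcripts as the percent of its 30-base windows, on either strand, found in no other gene. Sequence shared with the unmatched genes or the entries with numeric IDs was not measured. A share of 90% or more was treated as mostly unique and a share under 50% as shared. Lyz2, for example, was unique in 66.0% of windows, Ftl1 in 35.5%, Eef1a1 in 48.1%, Csf1r in 85.0% and Ighm in 100% of them. Overlapping and antisense genes cannot be told apart where the strand is unknown.

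Before the data were examined, 51 gene lists, the tests and the alternative settings were fixed. Of the list members, 4 had no matched gene. Levels are the mean TPM and SD of n = 2 replicates. A gene was called detected at 1 TPM in both replicates. List medians were taken over members in each replicate, and the percentile of the median of the mean TPM was found among 10000 random lists of the same size, drawn from genes at 1 TPM or more in either replicate and the members of the list. A list whose median lies under 1 TPM falls below such lists by construction. Lists were compared as mean log2(TPM + 1), with a pseudocount of 1 TPM and shared members left out, by a two-sided permutation test over genes with 100000 resamples, and adjusted by the Benjamini-Hochberg method over 14 cell type lists, 5 tissue macrophage lists and 6 pairs of programs at a threshold of 0.05. Full enumeration was not feasible for the lists of 9 genes, which were tested with the same resamples. A fold on this scale understates the change of low genes.

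Replicates were compared over genes at a mean of 1 TPM or more, with correlations across genes, and by a chi-square test of rounded expected counts over genes with 10 or more counts. List differences between replicates were placed among 10000 random lists matched in 20 expression bins. Isoform shares were compared in all genes of 10 TPM or more with several transcripts, and in the fixed isoform genes at any level, of which Fn1 and Il1rn had a mean under 10 TPM. Rounded expected counts were scaled with the TMM method of edgeR 4.0.16, with factors of 0.980 and 1.02, and with the median-of-ratios size factors of DESeq2 1.42.0, 1.20 and 0.830, as alternatives. No count test of single genes was run, because the only groups are 1 library against 1 library, and the chi-square test takes all genes together. Other alternatives were pseudocounts of 0.1 and 5 TPM, other TPM minimums, posterior means, FPKM, TPM rescaled to nuclear protein-coding genes, and each replicate alone. Restriction to protein-coding genes, to genes of mostly unique sequence, to list members of at least 50% unique sequence, and intervals rescaled to TPM were added after seeing the data.

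The text names the 20 highest genes, up to 4 highest and 2 lowest members of each list, any member of the lists of macrophage identity, transcription factors, cytokine receptors, MHC class II, M1 and M2, the 10 largest replicate ratios in each direction among genes of 5 TPM or more with separate intervals, the fixed isoform genes and all sex-linked genes. Genes outside this rule are said to be chosen after their values were seen.

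Methods were tested on simulated data. In simulated libraries drawn from the real means and depths, 1 against 1, over 9820 genes of which 200 were changed, the median log2 ratio was 0.96 for genes raised 2-fold, -0.96 for genes lowered 2-fold, 1.92 for genes raised 4-fold and -1.87 for genes lowered 4-fold. Of unchanged genes, 0.2% were over 2-fold apart, with an SD of 0.16. A list of 20 genes raised 2-fold lay at percentile 100, and 2 of 44 unchanged lists lay outside the middle 95%. The simulated counts were Poisson draws with 1 mean length per gene and no sharing of reads between genes. The real libraries spread more, with a chi-square of 7.49 per degree of freedom, so these simulated rates do not carry over to them. Of 400 random pairs of lists of 15 and 30 genes out of 13904, 5.25% had a permutation p of 0.05 or less, against 99.2% of pairs set 3 log2 units apart. A sequence sharing 100 of its 200 bases was 58.5% unique in windows. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.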

Results

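Polyadenylated RNA was sequenced from mouse bone marrow derived macrophages, the adherent phagocytes that grow from marrow progenitors in culture. The series held 1 group of 2 samples, called biological replicates 1 and 2 in the labels, each from an adult mouse of 8 weeks labelled male and of strain Bruce4. No treated, untreated or other control group was analysed here, so the design implied 3 kinds of comparison: among genes within these cells, among gene groups, and between the replicates. The gene tables held 11878065 expected counts in replicate 1 and 7909888 in replicate 2. Each label described an individual mouse, yet both samples were tied to a single donor record, so SDs measure only the spread between these samples, and p-values, which come from tests over genes, describe only these samples. Values are given as mean TPM ± SD with n = 2 replicates unless both replicates are listed, in which case replicate 1 comes first.

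The most abundant transcript was Lyz2, the lysozyme of myeloid cells, at 28088 ± 22.0 TPM (SD, n = 2). The Lyz2 gene (ENSMUSG00000069516.7, mm10 chromosome 10, 117277331 to 117282321, minus strand) was followed among protein-coding genes, mitochondrial genes aside, by Ftl1 at 15709 ± 553 and Fth1 at 14163 ± 239.8, which encode the ferritin chains that store iron, and by Apoe, the apolipoprotein that carries lipid out of macrophages, at 12829.5 ± 169 TPM. The next nuclear protein-coding genes were the actin-binding peptide gene Tmsb4x at 9588 ± 1185, the invariant chain gene Cd74 at 6016 ± 158 and the class I light chain gene B2m at 5925 ± 23.2 TPM. Lysosomal products also stood among the 20 highest matched genes, mitochondrial genes aside, with Ctss at 3934 ± 180.4 and Psap at 3269.7 ± 42.6 TPM. The same 20 held the galectin-3 gene Lgals3 at 3254 ± 95.4, the selenium carrier Selenop at 4163 ± 178 and the membrane protein gene Itm2b at 3483 ± 21.5 TPM. Actb and Eef1a1, a cytoskeletal and a translation gene, stood at 5751 ± 351 and 5726 ± 867 TPM.

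A total of 12689 of 42462 matched genes (29.9%) reached 1 TPM in both replicates, among them 10695 of 21474 protein-coding genes (49.8%). At higher levels the counts were 7760 genes at 10 TPM, 1255 at 100 TPM and 113 at 1000 TPM. Long intergenic and antisense non-coding genes reached 1 TPM in 468 of 4839 cases and pseudogenes in 859 of 7906. The leading long non-coding transcripts of the nuclear genome were Gm42418 at 16157 ± 2624 TPM, which overlaps a ribosomal RNA repeat on mm10 chromosome 17, 39846958 to 39848788, and the nuclear RNA Malat1 at 3943 ± 605 TPM. No read was assigned to 17144 genes in either replicate, where 0 counts allowed up to 0.253 and 0.379 CPM (counts per 1e6). The values of Gm42418 and of 4 short microRNA entries, Mir6236, Gm23935, Gm24270 and Gm24245, are uncertain, because 3.55% of the Gm42418 sequence and 0% of the last 3 was unique among annotated transcripts, and reads on entries under 200 bases held 0.271% and 0.305% of counts but 7.22% and 8.09% of TPM. Genes at 1 TPM in both replicates numbered 19398 when the deposited posterior mean TPM was used, a measure that is above 0 for genes without reads.

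Macrophage identity genes were expressed throughout. All 30 of 30 reached 1 TPM in both replicates and 26 reached 100 TPM, with list medians of 1212 and 1075 TPM. Csf1r, the receptor for the growth factor on which macrophages depend (ENSMUSG00000024621, mm10 chromosome 18, 61100598 to 61132149), stood at 1327 ± 152 TPM, the surface marker Adgre1 (F4/80) at 1180.0 ± 67.1, Cd68 at 1114 ± 115 and the integrin Itgam at 427 ± 34.1 TPM. The signalling adaptors Tyrobp and Fcer1g stood at 2781 ± 186 and 2583 ± 206 TPM, the pore-forming protein gene Mpeg1 at 1643 ± 81.9, the lipid receptor Trem2 at 685 ± 38.1 and the glycoprotein gene Gpnmb at 2037 ± 164 TPM. The lowest members were the efferocytosis receptor Mertk at 41.4 ± 0.141, Adgre4 at 15.6 ± 1.19 and the haemoglobin scavenger receptor Cd163 at 5.11 ± 0.389 TPM.

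Among myeloid transcription factors, 26 of 28 reached 1 TPM and 6 reached 100 TPM. Spi1, which encodes PU.1, was the highest at 395 and 341 TPM in replicates 1 and 2, followed by Zeb2 at 305 ± 17.0, Maf at 235 ± 7.54, Irf5 at 193 ± 18.8 and Irf8 at 155 ± 7.51 TPM. The C/EBP family stood lower, with Cebpb at 82.6 ± 7.7, Cebpd at 57.8 ± 4.62 and Cebpa at 51.0 ± 0.438 TPM. The lipid-sensing receptor Pparg stood at 25.3 and 20.6 TPM in replicates 1 and 2, Nr1h3 at 10.4 ± 0.955, Irf4 at 5.45 ± 0.707 and Egr2 at 4.01 ± 0.884 TPM, and Egr1 at 1.24 and 0.74 TPM. Gata6, the factor of peritoneal macrophages, had 0 counts in both replicates, which allowed up to 0.123 and 0.183 TPM.

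Receptors for cytokines were expressed in 24 of 26 cases. After Csf1r came the interferon-gamma receptor chain Ifngr1 at 291 ± 13.2, Il10rb at 260.0 ± 1.18, the GM-CSF receptor chain Csf2ra at 237 ± 11.5, the type I interferon receptor chain Ifnar2 at 182 ± 1.00 and Il10ra at 149.8 ± 0.651 TPM. Both TNF receptors stood at similar levels, with Tnfrsf1a at 147 ± 17.6 and Tnfrsf1b at 147 ± 19.5 TPM. The interleukin-4 receptor Il4ra was at 32.2 ± 3.15 TPM. The interleukin-1 receptor Il1r1 at 0.27 and 0.4 TPM and the progenitor receptor Flt3 at 0.09 and 0.22 TPM were the members under 1 TPM.

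Transcripts of other cell types that marrow cultures could hold were far below those of macrophages. Of 12 natural killer cell genes, 12 mast cell and basophil genes and 12 erythroid genes, 0 reached 1 TPM in both replicates. T cell genes reached it in 1 of 16 cases, which was Cd4 at 18.5 ± 1.90 TPM, while the T cell receptor genes Cd3e and Trac had 0 counts. B cell genes reached it in 3 of 15 cases, namely the immunoglobulin heavy chain gene Ighm at 198 ± 5.04, Cd22 at 6.83 ± 1.36 and Cd79b at 4.14 ± 0.94 TPM, whereas the light chain gene Igkc stood at 0 and 1.31 and Cd19 at 0 and 0.08 TPM. Monocyte and progenitor genes reached it in 6 of 19 cases, led by the chemokine receptor Ccr2 at 87.8 ± 5.26 and F13a1 at 30.9 ± 0.495 TPM.

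Some members of the remaining lists were abundant. Neutrophil genes passed 1 TPM in 6 of 15 cases, led by the growth factor receptor Csf3r at 71.6 ± 1.49, Mmp8 at 20.8 ± 1.51 and the calprotectin chains S100a9 at 17.8 ± 0.877 and S100a8 at 15.1 ± 0.304 TPM. Dendritic cell genes passed it in 5 of 16 cases, led by Bst2 at 267 ± 4.99, Irf8 and the lectin Clec10a at 78.0 ± 9.55 TPM. Adipocyte genes did so in 5 of 11 cases, led by the lipase Lpl at 1048 ± 105 and the fatty acid transporter Cd36 at 219.8 ± 13.3 TPM, and megakaryocyte genes in 6 of 12, led by the platelet chemokine Pf4 at 221 ± 20.9 and Vwf at 7.15 ± 0.396 TPM. Osteoclast genes passed it in 8 of 13 cases, led by the chloride exchanger Clcn7 at 86.4 ± 5.82 and the RANK receptor Tnfrsf11a at 41.0 ± 0.247 TPM. Fibroblast and stromal genes did so in 9 of 16, with Acta2 at 19.1 ± 4.70, Sparc at 18.1 ± 0.629, Bgn at 17.7 ± 2.32 and the collagen gene Col1a1 at 12.2 ± 2.75 TPM. Endothelial genes passed 1 TPM in 3 of 12 cases, with Pecam1 at 4.42 ± 0.177 TPM, and eosinophil genes in 2 of 10, with Ccr3 at 3.42 ± 0.12 TPM next to Adgre4, which the macrophage list also held.

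On the log2(TPM + 1) scale, the mean of each of the 14 lists lay below the macrophage identity mean of 9.28 in both replicates. The differences were -6.50 ± 0.04 for adipocyte, -6.86 ± 0.10 for osteoclast, -7.29 ± 0.10 for fibroblast, -7.37 ± 0.07 for dendritic cell, -7.55 ± 0.11 for neutrophil, -7.68 ± 0.08 for megakaryocyte and -7.80 ± 0.13 for monocyte and progenitor genes. They were -8.19 ± 0.13 for B cell, -8.57 ± 0.01 for endothelial, -8.78 ± 0.08 for T cell, -8.96 ± 0.04 for mast cell and basophil, -8.99 ± 0.01 for erythroid, -9.12 ± 0.06 for natural killer cell and -9.12 ± 0.001 for eosinophil genes. For every list the two-sided permutation test over genes gave p = 1e-05, the smallest that 100000 resamples can give, and a Benjamini-Hochberg adjusted p of 1e-05 over the 14 lists. Over members at 1 TPM or more, which left 10 lists, the differences ran from -3.45 for adipocyte genes to -6.96 for endothelial genes, with adjusted permutation p-values of at most 0.0077. Genes are not independent replicates, so these p-values describe the lists in these libraries. The median of the macrophage identity list lay at percentile 100 of the random lists of expressed genes. A list can therefore fall below this reference whatever the purity of the cultures, and the tests do not measure that purity.

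**Figure D1:**
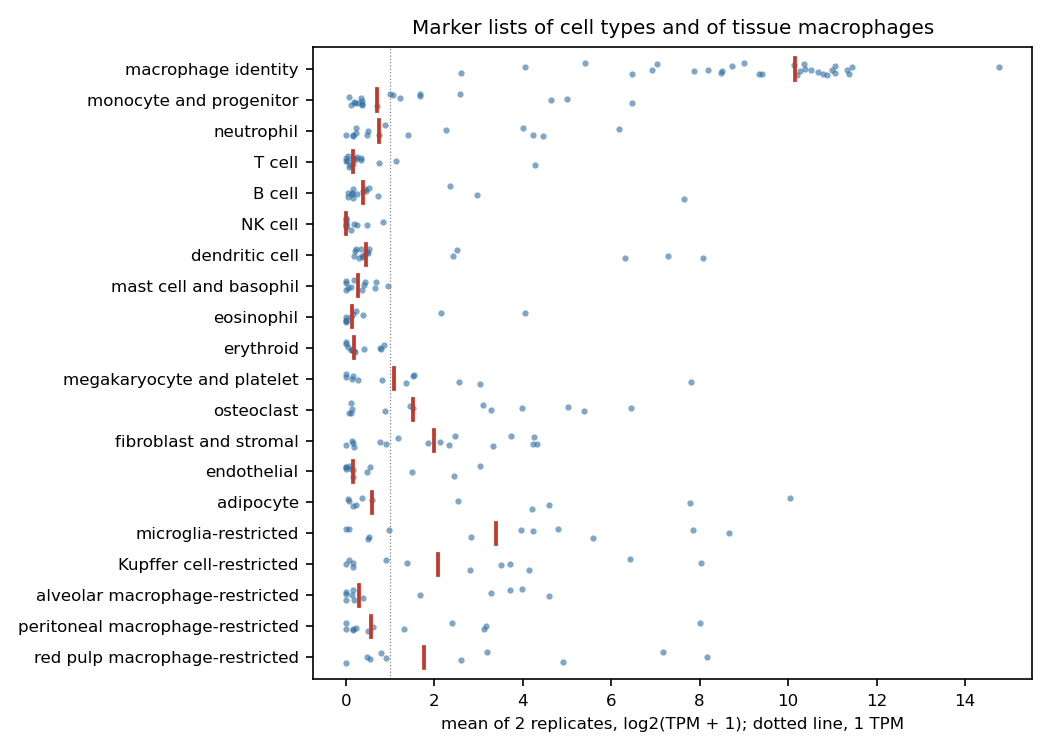
Each point is a gene of a list, placed by its level as log2(TPM + 1) of the mean of 2 replicates, with the list median as a red bar and 1 TPM as a dotted line. The macrophage identity genes have medians of 1212 and 1075 TPM in replicates 1 and 2, and the other lists lie lower, with single abundant members such as Lpl, Ighm and Pf4.

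Lists called restricted to resident macrophages of a tissue were expressed in part, but the name does not mean that their members are absent elsewhere. The alveolar members that reached 1 TPM also stood in other lists, such as Pparg in the adipocyte list and Marco in the Kupffer cell list. Microglia-restricted genes reached 1 TPM in 7 of 12 cases, with the Fc receptor-like gene Fcrls at 404 ± 35.9, Hexb at 231 ± 3.95, the chemokine receptor Cx3cr1 at 47.4 ± 2.60 and the purine receptor P2ry12 at 26.9 ± 1.09 TPM, while the microglial factor Sall1 stood at 0.02 and 0.07 TPM. Kupffer cell-restricted genes did so in 7 of 12 cases, with the folate receptor Folr2 at 261 ± 18.8 and Cd5l at 85.6 ± 5.14 TPM, while Clec4f had 0 counts and Timd4 stood at 0 and 0.09 TPM. Red pulp genes did so in 5 of 10 cases, with the haem oxygenase Hmox1 at 286 ± 24.8, Siglec1 at 144 ± 30.4 and the iron exporter Slc40a1 at 29.0 ± 0.714 TPM, alveolar genes in 5 of 12, with Pparg highest, and peritoneal genes in 5 of 12, with Cd93 at 258 ± 12.5 TPM. The differences from the macrophage identity mean were -5.95 ± 0.06 for microglia, -6.61 ± 0.10 for red pulp, -6.67 ± 0.001 for Kupffer cell, -7.64 ± 0.03 for peritoneal and -7.77 ± 0.06 for alveolar genes on the log2(TPM + 1) scale. Each had a permutation p of 1e-05, two-sided over genes and the smallest possible, and an adjusted p of 1e-05 over the 5 lists. Over members at 1 TPM or more the differences ran from -3.65 for red pulp to -5.83 for alveolar genes, with adjusted permutation p-values of at most 0.0036. As the reference list is so abundant, these tests do not tell whether a tissue program was absent.

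Genes of the phagocytic and degradative machinery were abundant. Lysosome and cathepsin genes had medians of 641 and 655 TPM in replicates 1 and 2, and 22 of 28 exceeded 100 TPM, led by Ctss, Psap, Ctsd at 2151 ± 116 and Ctsb at 2142 ± 74.6 TPM. The lowest was the osteoclast protease gene Ctsk at 8.71 ± 0.983 TPM. Scavenger and lectin receptors had medians of 124 and 108 TPM, with the receptor Stab1 at 958 ± 153 and the C-type lectin Clec4d at 633 ± 37.0 TPM. Genes of the phagocyte oxidase and antimicrobial defence had medians of 174 and 159 TPM, with both membrane subunits of the oxidase, Cyba at 716 ± 19.9 and Cybb at 509 ± 23.5 TPM, and with the nitric oxide synthase gene Nos2 at 0.03 and 0.09 TPM. Fc and complement receptors had medians of 93.6 and 91.7 TPM, with Fcgr3 at 821 ± 0.488 TPM and the anaphylatoxin receptor C3ar1 at 582 and 528 TPM. Complement components were split: the 3 chains of C1q stood at 2676 ± 57.1 for C1qb, 1891 ± 92.3 for C1qc and 1462 ± 48.7 TPM for C1qa and properdin Cfp at 269.6 ± 12.2 TPM, while 8 of 18 components reached 1 TPM and the list medians were 0.61 and 1.08 TPM. The median of the complement list over the replicate means was 0.72 TPM, and 1.64 with posterior mean TPM.

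Innate sensing genes were present at moderate levels. All 20 of 20 Toll-like receptor and signalling genes reached 1 TPM, with medians of 47.0 and 43.0 TPM. The trafficking chaperone Unc93b1 was highest at 891 ± 31.4, followed by the LPS co-receptor Cd14 at 364 ± 16.5, Tlr7 at 196 ± 19.1 and Tlr8 at 144 ± 47.4 TPM, and Tlr5 was lowest at 1.81 ± 0.198 TPM. All 20 of 20 inflammasome and cytosolic sensor genes also reached 1 TPM, with medians of 37.5 and 37.7 TPM, Casp1 at 98.5 ± 1.74 and Gsdmd at 84.0 ± 1.53 TPM. Type I interferon-stimulated genes reached 10 TPM in 25 of 25 cases, with medians of 47.1 and 45.9 TPM, Bst2 at 267 ± 4.99, Oasl2 at 257 ± 8.79, Rtp4 at 169 ± 5.75 and Ifi204 at 167 ± 4.24 TPM. Chemokines and their receptors had medians of 8.85 and 11.5 TPM, led by Ccl9 at 530.2 ± 9.01, C5ar1 at 351 ± 11.5 and Cxcl16 at 338 ± 14.6 TPM.

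Antigen presentation genes of both classes were expressed. Class I genes reached 10 TPM in 17 of 17 cases, with H2-D1 at 1912 ± 31.3 and H2-K1 at 1362 ± 30.9 TPM beside B2m. Class II genes reached it in 10 of 15, with Cd74, H2-Aa at 1965 ± 52.0, H2-Ab1 at 1162 ± 28.7 and H2-Eb1 at 906 ± 63.9 TPM, the master regulator Ciita at 28.6 ± 2.68 TPM, and H2-Ea-ps at 0 counts in both replicates. The costimulatory genes of that list stood at 22.7 ± 1.34 for Cd86, 19.2 ± 4.36 for Cd40 and 4.89 ± 0.212 TPM for Cd80. The medians of the class I list were 119 and 112 TPM and those of the class II list 30.4 and 26.7 TPM.

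Genes that LPS with interferon-gamma or interleukin-4 induce were mostly low. Of the former, called M1, 10 of 20 reached 1 TPM, with Irf1 at 78.6 ± 3.54, Fpr2 at 39.1 ± 0.269, Il1b at 25.7 ± 2.57, Cxcl10 at 22.8 ± 0.354 and Tnf at 9.10 ± 0.714 TPM. The cytokine genes Il6, Il12a, Il12b and Il23a had 0 counts in both replicates, which for Il6 allowed up to 0.367 and 0.548 TPM. Of the interleukin-4 genes, called M2, 9 of 19 reached 1 TPM, with the mannose receptor Mrc1 at 355 ± 7.64, Clec10a at 78.0 ± 9.55 and the transglutaminase Tgm2 at 10.2 ± 1.30 TPM, while the arginase Arg1 stood at 0.18 and 0.27, Retnla at 0.91 and 0 and Ccl17 at 0.54 and 0 TPM. The medians were 2.85 and 2.81 TPM for the M1 list and 0.91 and 1.15 TPM for the M2 list.

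Cell cycle genes were expressed. All 23 of 23 G1/S genes reached 1 TPM, with medians of 15.9 and 17.6 TPM and Pcna, the sliding clamp of replication, at 258 ± 15.1 TPM. Of the G2/M genes, 24 of 25 reached 10 TPM, with medians of 39.0 and 30.1 TPM, the topoisomerase Top2a at 94.8 ± 1.23, the proliferation marker Mki67 at 74.2 ± 8.04 and the kinase Cdk1 at 72.4 ± 3.35 TPM. Cyclin D and CDK inhibitor genes had medians of 34.8 and 41.0 TPM, with the retinoblastoma gene Rb1 at 189.6 ± 27.7 and the inhibitor Cdkn1a at 148 ± 7.15 TPM, whereas Cdkn2a stood at 0.63 and 0.22 TPM. Of 12 genes listed as replication-dependent histones, 8 reached 1 TPM, with Hist1h2bc at 71.7 ± 4.54 and Hist1h1c at 57.0 ± 3.44 TPM. Transcripts of this class mostly lack a poly(A) tail and polyadenylated RNA was sequenced, so these levels do not measure the class in the cells.

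Metabolic genes differed by pathway. Nuclear-encoded oxidative phosphorylation genes had medians of 130.1 and 133 TPM, with Cox4i1 at 465 and 487 TPM and Atp5b at 318 ± 40.3 TPM, and glycolysis genes 43.1 and 38.0 TPM, with Aldoa at 836 ± 83.1 and Pkm at 757 ± 39.6 TPM. Targets of the sterol-sensing LXR receptors had medians of 46.2 and 52.7 TPM, with Apoe, the lipid transfer protein gene Pltp at 1096 ± 79.4 and the lipid droplet gene Plin2 at 374 ± 3.5 TPM, and sterol synthesis genes 17.5 and 17.5 TPM, with Msmo1 at 52.1 ± 1.63 and Ebp at 43.7 ± 0.042 TPM. Iron and haem genes had medians of 50.5 and 46.5 TPM, with both ferritin genes and the metal transporter Slc11a1 at 424 ± 26.6 TPM, whereas the hormone gene Hamp had 0 counts. Hypoxia response genes had medians of 17.1 and 17.3 TPM, with Ndrg1 at 93.3 ± 20.1 and Vegfa at 49.4 ± 1.59 TPM, and unfolded protein and stress genes 43.8 and 45.7 TPM, with Hspa8 at 1425 ± 159 and Hsp90b1 at 464 ± 57.6 TPM. Immediate early genes had medians of 22.4 and 22.3 TPM, with Klf6 at 123 ± 0.573 and Zfp36 at 114 ± 5.27 TPM, and ribosomal protein genes 951 and 1045 TPM, with Rplp1 at 2176 ± 44.2 and Rps24 at 2161 ± 309 TPM. Genes of the mitochondrial genome held 9.56% and 10.6% of TPM, with mt-Co1 at 20062 ± 81.1 TPM. These values are uncertain, since mt-Co1 was 35.2% unique and mt-Co2, at 7370 and 11762 TPM in replicates 1 and 2, was 0% unique. Of the 27 program lists, 18 had a median at or above the 95th percentile of 10000 random lists of the same size, drawn from genes at 1 TPM or more in either replicate and the list's own members. These draws covered all gene classes. Of 10695 protein-coding genes detected, 7219 reached 10 TPM in both replicates, against 310 of 859 pseudogenes. The percentiles may therefore also reflect gene class. The M1, M2 and complement component lists had the lowest medians.

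**Figure D2:**
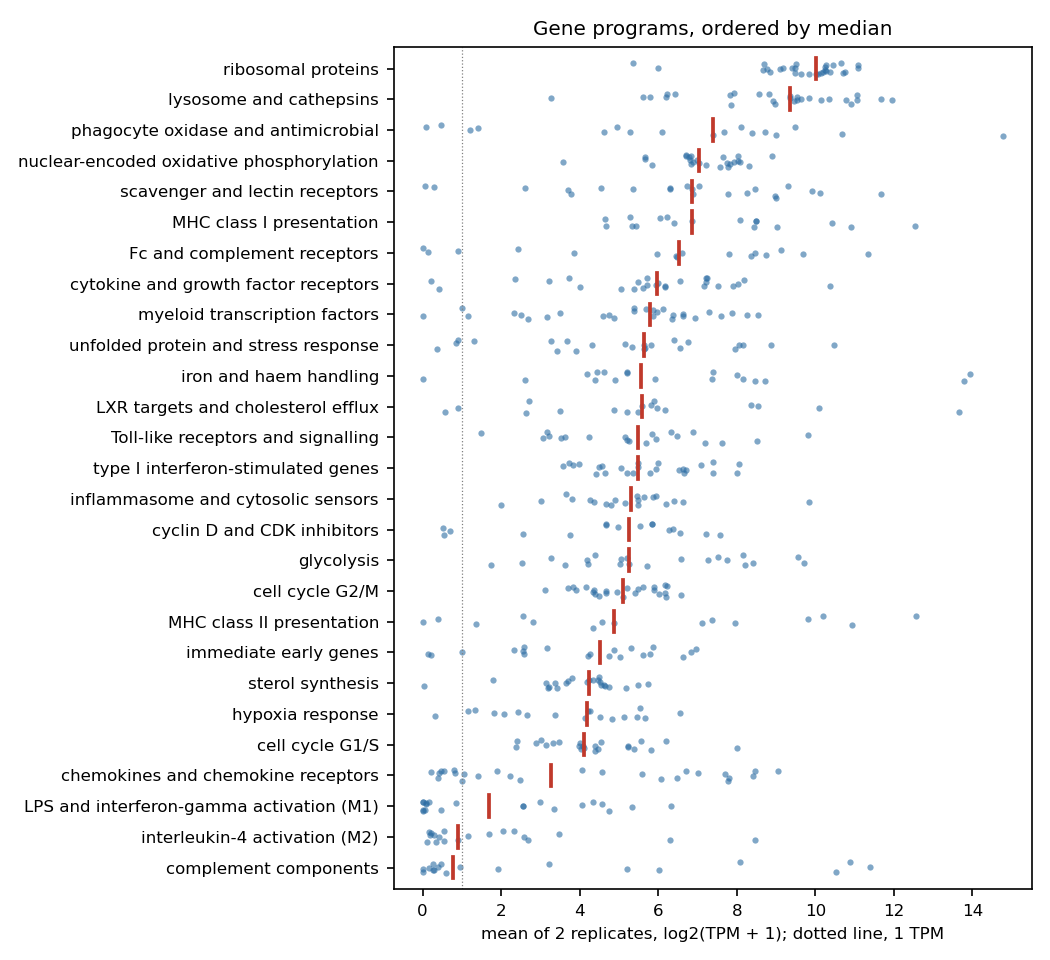
Each point is a gene of a program list, placed by its level as log2(TPM + 1) of the mean of 2 replicates, with the list median as a red bar and 1 TPM as a dotted line. Ribosomal protein and lysosomal genes lie highest, with medians of 951 and 1045 TPM and 641 and 655 TPM in replicates 1 and 2, and the M2 and complement lists lowest.

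Of 6 fixed pairs of programs, 3 differed in a two-sided permutation test over genes with 100000 resamples. Type I interferon-stimulated genes such as Bst2 lay above M1 genes such as Irf1 by 3.56 ± 0.04 on the log2(TPM + 1) scale (SD, n = 2), with a permutation p of 1e-05 and an adjusted p of 6e-05. This difference was 1.6 over members at 1 TPM or more, with an adjusted permutation p of 0.0079, and 2.42 at a pseudocount of 5 TPM. LXR targets such as Apoe lay above sterol synthesis genes such as Msmo1 by 1.71 ± 0.02, with a permutation p of 0.023 and an adjusted p of 0.046. Glycolysis genes minus oxidative phosphorylation genes gave -1.23 ± 0.12, so the oxidative phosphorylation list had the higher mean, with a permutation p of 0.022 and an adjusted p of 0.046. Each difference had the same sign in 2 of 2 replicates. The other 3 pairs did not pass: G1/S minus G2/M genes gave -0.71 ± 0.02 with an adjusted permutation p of 0.054, class I minus class II genes 1.70 ± 0.11 with 0.17, and M2 minus M1 genes -0.32 ± 0.06 with 0.65. Over members at 1 TPM or more, the last 2 differences were 0.84 and -0.67, with adjusted permutation p-values of 0.45 for both. The LXR and glycolysis pairs did not pass without replicate 2, with adjusted permutation p-values of 0.057 for both, and at a pseudocount of 0.1 TPM, with 0.068 and 0.061, and the glycolysis pair did not pass at a pseudocount of 5 TPM, with 0.056. With 2 replicates an exact test over replicates cannot give a p below 0.5, so the tests ran over genes, which are not independent replicates.

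The replicates differed little for protein-coding genes and widely for pseudogenes and small RNAs. Folds between the replicates are of TPM + 1 unless counts are named, and they understate the change of low genes. Across 10928 protein-coding genes at a mean of 1 TPM or more, the log2 ratio of replicate 2 to replicate 1 had an SD of 0.31. Of these genes, 75.0% lay within 20% and 1.11% were over 2-fold apart. Csf1r stood at 1434 and 1219.5 and B2m at 5908 and 5941 TPM in replicates 1 and 2. The SD was 1.39 for 1223 pseudogenes, 31.7% of which were over 2-fold apart, and 1.87 for 779 genes of small RNA classes, 68.7% of which were. Across all 13906 genes the Pearson correlation of log2(TPM + 1) was 0.946, Spearman's rho was 0.958, the SD was 0.68 and 1111 genes (7.99%) were over 2-fold apart. The correlations are across genes, which are not independent replicates. A chi-square test of rounded expected counts over 14427 genes gave 7.49 per degree of freedom, and 2.90 over 9085 protein-coding genes of mostly unique sequence. The test covers counting error only, on counts that share reads among gene copies, and does not tell whether the samples come from different mice. With TMM-scaled CPM in place of TPM, the SD over all genes was 0.39. CPM is not divided by gene length, so reads on short entries weigh less than in TPM. The SDs of CPM and TPM are therefore not on equal terms.

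**Figure D3:**
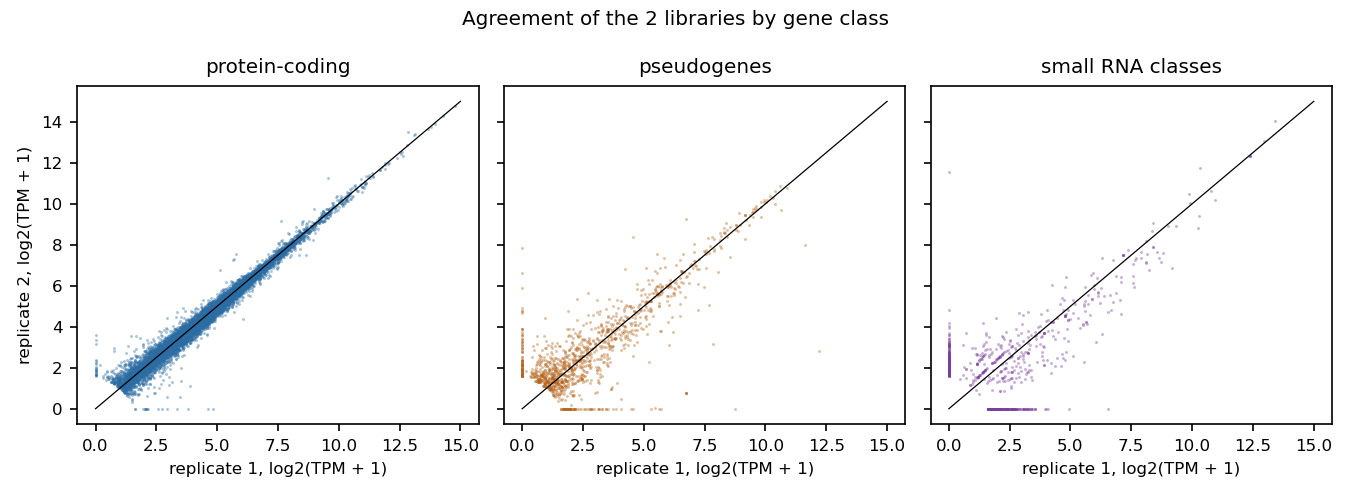
Each point is a gene with a distinct symbol at a mean of 1 TPM or more, placed by its log2(TPM + 1) in replicate 1 and in replicate 2, with the line of equality in black. Protein-coding genes lie close to the line (SD of the log2 ratio 0.31), while pseudogenes (1.39) and small RNA classes (1.87) spread widely and hold many genes listed at 0 in 1 library.

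The genes farthest apart between replicates were mostly pseudogenes and small RNAs of under 50% unique sequence. The mitochondrial-copy pseudogenes Gm28661 and Gm28437 (mm10 chromosome 1, 24614885 to 24615565 and 24613189 to 24613971) stood at 4717 and 5.99 and at 427 and 0 TPM in replicates 1 and 2. The microRNA entry Gm22133, at mm10 chromosome 7, 45458089 to 45458197, stood at 0 and 2958 TPM, within the interval of Ftl1. The pseudogenes Gm14039 and Gm14414 stood at 0 and 226 and at 0 and 98.2 TPM. Of the 10 largest ratios in each direction, 13 belonged to pseudogenes, 5 to small RNAs and 1 to the protein-coding gene Gm20721, at 23.8 and 0 TPM, and 17 of the 20 genes had under 50% unique sequence. Among 10002 genes at 5 TPM or more, 1203 had deposited credibility intervals that did not overlap, 175 of them higher and 1028 lower in replicate 2. These intervals follow the posterior mean TPM, which lay at 0.914 and 0.879 of TPM in the median gene of replicates 1 and 2, and after division by these ratios 947 genes remained apart, 311 higher and 636 lower.

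Between the replicates, 3 of 44 gene lists had a median ratio outside the middle 95% of 10000 random lists matched on expression. If the lists behaved as random ones, 2.2 would be expected outside. The random lists were not matched on gene class, and the classes spread unequally between the replicates. The ranges and the number 2.2 are therefore only a rough guide. Ribosomal protein genes such as Rps24, at 1943 and 2379.8 TPM, had a median log2 ratio of replicate 2 to replicate 1 of 0.12, against -0.10 to 0.08 for random lists, and 23 of 29 were higher in replicate 2; with TMM-scaled counts or size factors this median was 0.06 and 21 of 29 were higher. Fibroblast and stromal genes such as Col1a1, at 14.2 and 10.3 TPM, had a median of -0.24, against -0.23 to 0.23, and 8 of 10 were lower; at a pseudocount of 0.1 TPM and over genes at 5 TPM or more this list lay inside the range, at percentiles 2.6 and 5.5. The small and ribosomal non-coding list, which also holds long RNAs such as Malat1 and Neat1, had a median of -0.40, against -0.17 to 0.14. Rn7sk stood at 638 and 485 TPM, whereas Malat1, at 3515 and 4371, and Neat1, at 534 and 655 TPM, were the members higher in replicate 2. The small RNA values are uncertain, since Rn7sk was 26.5% unique, Rpph1 29.7% and Rn7s1, Rn7s2 and Rmrp 0%, and Rn7s1 and Rn7s2 carried identical values. Polyadenylated RNA was sequenced, so the values of Rn7sk, Rpph1, Rn7s1, Rn7s2 and Rmrp also need not follow their levels in the cells. Of these, Rn7s2, Rmrp and Rpph1 were chosen after their values were seen. This compares 1 library with 1 library, so there is no replicate check and no p-value. With TMM-scaled counts or with median-of-ratios size factors, 7 lists lay outside, these 3 with adipocyte, glycolysis, oxidative phosphorylation and cyclin D and CDK inhibitor genes.

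Most expressed genes used the same leading transcript in both replicates. Among 5862 genes with several annotated transcripts and at least 10 TPM, 4626 (78.9%) did so, the median share of the leading transcript was 54.0%, and in 515 genes (8.79%) it was at least 90%. The transcript Csf1r-201 held 96.6% ± 0.233 (SD, n = 2) of Csf1r TPM, Pkm-201 held 84.1% ± 1.95 and Pkm-202 15.9% ± 1.95 of the pyruvate kinase gene, Fcgr3-201 held 70.2% ± 4.70, Mitf-202 69.4% ± 9.86 and Ccl9-201 53.5% ± 0.318. Others were divided, with Spi1-201 at 47.0% ± 5.93, Apoe-209 at 46.9% ± 4.26 and Tpm3-201 at 41.5% ± 0.742. The leading transcript switched in 5 of the 17 fixed genes with several transcripts, namely Ptprc, Irf7, Cd44, Tpm1 and Fn1, the last at 8.97 and 7.13 TPM. In Ptprc, the leukocyte phosphatase gene, Ptprc-204 moved from 25.2% to 23.2% and Ptprc-203 from 19.4% to 29.1%, and in the adhesion receptor gene Cd44, Cd44-201 moved from 29.1% to 28.9% and Cd44-207 from 28.6% to 39.9%. The share of the leading transcript of Il1rn moved from 72.2% to 32.3% for Il1rn-201, on 71.3 and 39.9 expected counts, and in 1252 of the 5862 genes a transcript share differed by over 20 percentage points between replicates. Read lengths of 30 bases, implied by the tables, limit how well transcripts of a gene can be told apart.

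Sex-linked genes did not follow the label. In the libraries labelled male, Xist, the RNA that coats the inactive X chromosome (mm10 chromosome X, 103460366 to 103483254), stood at 212 and 239 TPM. The Y-linked genes stood at 0.26 and 0.34 TPM for Kdm5d, 0.18 and 0.13 for Eif2s3y, 0 and 0.08 for Uty and 0.03 and 0 for Ddx3y, together 18.2 and 16.0 expected counts. Their X-linked partners stood at 138 ± 16.1 for Ddx3x, 70.7 ± 2.66 for Eif2s3x, 35.4 ± 3.70 for Kdm5c and 22.3 ± 1.10 TPM for Kdm6a, and Tsix, the antisense partner of Xist, at 0.04 and 0.13 TPM. The Y-linked sum was 0.169% and 0.215% of the sum of the X-linked partners.

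**Figure D4:**
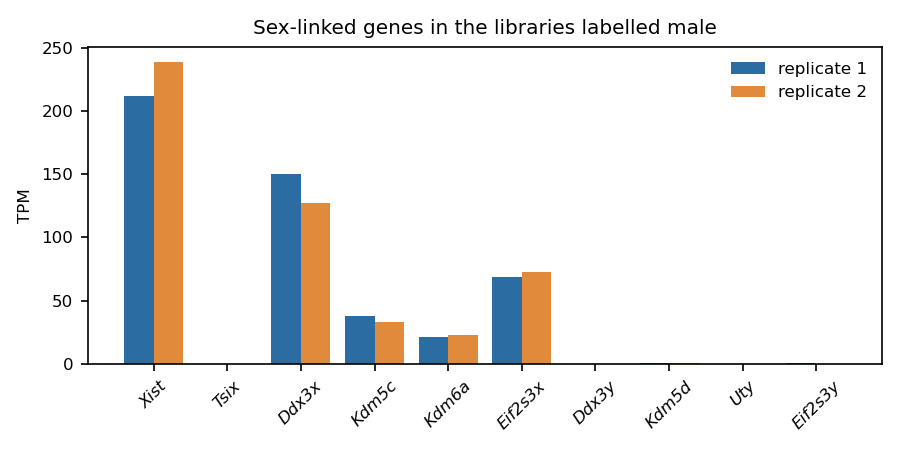
Bars give the TPM of the 10 sex-linked genes in replicate 1 and replicate 2, both labelled male, on a linear axis from 0. Xist stands at 212 and 239 TPM and the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y at 0.34 TPM or less.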

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

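Summed over each class of sequence, signals outside the macrophage measurements were found above the 3 counts that a count of 0 allows. The control phage phiX174, a sequence commonly added to sequencing runs, held 258704 expected counts or 2.18% of replicate 1 (95% Wilson interval 2.17% to 2.19%) and 241840 or 3.06% of replicate 2 (3.05% to 3.07%), which is 6255 and 8724 TPM. The 96 ERCC sequences, spike-ins of the kind the labels name, held 59.4 counts in replicate 1 and 22 in replicate 2, with at most 5 and 2 counts on any sequence, so that no single ERCC sequence passed 3 counts in replicate 2. Entries with numeric IDs, of a median length of 73 bases, held 2679 counts in replicate 1 and 2199 in replicate 2, or 0.786% and 0.963% of TPM.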

How the results depend on the processing

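Alternatives restricted to protein-coding genes, to mostly unique genes or to list members of at least 50% unique sequence, and rescaled intervals, were chosen after seeing the data, and the others were planned. No result reversed. No paired analysis was possible because the samples form 1 group. All 14 cell type and all 5 tissue macrophage differences kept their direction and their side of the threshold under every alternative run, except that natural killer, mast cell, eosinophil and erythroid genes were not tested over members at 1 TPM or more. As the reference list is so abundant, this stability does not measure the purity of the cultures or the absence of a tissue program. Detected genes ranged from 11439 at 2 TPM to 13998 at 0.5 TPM over all gene classes, numbered 10695 over protein-coding genes only, and 19398 with posterior mean TPM, a measure that is above 0 for genes without reads. The replicate correlation of 0.946 and SD of 0.68 became 0.862 and 1.28 at a pseudocount of 0.1 TPM, 0.974 and 0.38 at 5 TPM, 0.979 and 0.45 with no filter, 0.952 and 0.52 at 5 TPM or more, 0.986 and 0.39 with TMM and again with size factors, 0.982 and 0.4 with posterior means, 0.987 and 0.31 for protein-coding genes, and 0.973 and 0.44 for mostly unique genes. Scaled counts are not divided by gene length, so their correlations and SDs are not on equal terms with those of TPM. Program lists at or above the 95th percentile numbered 18, 23 with posterior mean TPM, 19 with TPM rescaled to nuclear protein-coding genes and 18 with either replicate left out. Program contrasts past the threshold fell from 3 to 1 at a pseudocount of 0.1 TPM, and numbered 1 to 3 when each replicate was left out, 1 without replicate 2. LXR minus sterol genes gave 1.74 (adjusted permutation p = 0.068) at a pseudocount of 0.1 TPM and 1.69 to 1.73 with a replicate left out (0.057 without replicate 2). Glycolysis minus oxidative phosphorylation gave -1.28 (0.061) at 0.1 TPM, -1.07 (0.056) at 5 TPM and -1.31 to -1.14 with a replicate left out (0.057 without replicate 2); the cause was not tested for these calls. Lists outside the middle 95% between replicates rose from 3 of 44 to 7 with TMM and to 7 with size factors, and the cause was not tested. They numbered 2 at a pseudocount of 0.1 TPM, 3 at 5 TPM and 4 of 35 over genes at 5 TPM or more. Over members of at least 50% unique sequence they numbered 3 of 43, where the small and ribosomal non-coding list was not placed. Genes with the same leading transcript made up 74.0% at 1 TPM or more and 83.3% at 50 TPM or more, against 78.9%. The fibroblast list difference moved inside the range of random lists at a pseudocount of 0.1 TPM (-0.26, percentile 2.6) and at 5 TPM or more (-0.23, percentile 5.5). Of mostly unique genes under 50 summed counts, 25.8% were over 2-fold apart between the replicates, against 0.173% at 50 or more.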

Other observations

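Protein-coding genes of at least 90% unique sequence and 50 counts numbered 7814. Of these, 154 were over 1.5-fold apart in TPM + 1 between the replicates, and 119 of those lay within 1.5-fold in TMM-scaled counts. Conversely, 100 genes were over 1.5-fold apart in counts with 0.5 added, 65 of them within 1.5-fold in TPM + 1. The SD of the log2 ratio was 0.23 in TPM + 1 and 0.22 in counts. The pseudocount of 1 TPM shrinks the folds of low genes more than the 0.5 added to counts does. These numbers therefore do not compare TPM with counts on equal terms. Of the genes named next, Tmc6, Thg1l, Sowahc and Gas5 were chosen after their values were seen. Tmc6 had 162 and 146 expected counts in replicates 1 and 2 but 11.8 and 26.1 TPM, with estimated gene lengths of 1801 and 1111 bases. The endosomal RNA sensor Tlr8 had 3050 and 1503 counts and 178 and 110 TPM. Thg1l, a tRNA-modifying enzyme gene, had 384 and 122 counts and 22.9 and 11.4 TPM. Sowahc had 194 counts in replicate 1 and 0.02 in replicate 2.

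Transcripts of non-coding annotation beyond Malat1 and Xist included Gas5, a host gene of small nucleolar RNAs, at 195 ± 31.1 TPM (SD, n = 2), and Ifi30, annotated as a processed transcript although it encodes a lysosomal thiol reductase, at 248 ± 0.276 TPM. The heavy chain gene Ighm was read as Ighm-201 for 59.7% ± 0.693 of its TPM and as Ighm-202 for 40.3% ± 0.693. The 2 Xist transcripts named here, Xist-201 and Xist-202, held 81.6% ± 1.25 and 18.4% ± 1.25 of Xist TPM.

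Of the tests that follow, those on a minority of female cells, on B cells and on variable segments were chosen after the result was seen.

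Both libraries labelled male held Xist at 212 and 239 TPM and 4 Y-linked genes at 0.34 TPM or less. Loss of Y-linked reads to X-linked copies is argued against by the sequence of Ddx3y, Kdm5d, Uty and Eif2s3y, whose median unique share was 97.2%. A minority of female cells in male cultures is argued against by the Y-linked sum, at most 0.215% of that of the X-linked partners. A recorded sex that differs from that of the cells stays open as a candidate explanation without a separate test: 0 of 7 protein-coding genes on chromosome Y with at least 50% unique sequence reached 1 TPM in both libraries, but 4 of the 7 are the genes that form the pattern. No biological explanation was tested, since the design holds 1 group.

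Ighm stood at 202 and 195 TPM in libraries with few other B cell transcripts. B cells or plasma cells are argued against by Igkc and Cd79a, chosen after their values were seen, the higher of which was at most 0.672% of Ighm TPM, while Cd22 and Cd79b reached at most 3.86% and 2.47%, so a small number of B cells that leaves most Ighm unaccounted for is not excluded. Reads shared with other immunoglobulin genes of M21 are argued against by the windows of Ighm, 100% of which were unique to it. Entries of the deposited tables that are absent from M21 were not covered. Transcription of the constant region without a rearranged variable segment may account for the level, since 213 variable segment genes together held 2 and 10 counts, at most 0.641% of the 2411 and 1561 counts of Ighm. This is a hypothesis, and no biological difference between groups could be tested with 1 group.

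Genes over 2-fold apart in TPM + 1 between the replicates numbered 1110 of the 13904 genes with a distinct symbol at 1 TPM or more. Reads shared between gene copies may account for part of them, as the share over 2-fold apart at 50 counts or more was 87.2 times as high for genes under 50% unique (137 of 909) as for those of 90% or more (14 of 8102). Low counts may account for another part, as that share was 149.6 times as high under 50 counts (297 of 1149 mostly unique genes) as at 50 counts or more. Of the 7 protein-coding genes left, all chosen after their values were seen, Lyrm9, Nckap5l and Tmc6 lay within 1.5-fold in TMM-scaled counts while their estimated gene lengths differed, and Sowahc, Helq, Ccdc73 and Kcnrg lay over 1.5-fold apart in counts. The estimated lengths of Helq, at 2059 and 1573 bases in replicates 1 and 2, and of Ccdc73, at 706 and 516, differed too. Expected counts were low for Helq (34 and 52), Ccdc73 (26.2 and 32.3) and Kcnrg (22 and 35), so counting error is not excluded. For Sowahc, Helq, Ccdc73 and Kcnrg a difference between animals cannot be told apart from one between libraries. Each sample has 1 library and both share a donor record.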
